A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

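Two-colour cDNA arrays measured polyadenylated RNA of yeast cells exposed to chloroacetaldehyde, in Cy5, against RNA of the cells before exposure, in Cy3. Per the labels, the 3 hybridizations come from independent biological samples, RNA was extracted with hot phenol and purified on oligo-dT, and each array was scanned at high and low laser power to recover spots brighter than the scanning range. Whether the earlier RNA came from a separate culture for each hybridization is not given in the sources used here. All 6 scans form a single group, with the replicate number and the laser power taken from the sample titles.

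Values are the authors' deposited log2 ratios per spot, normalized by LOWESS within each scan on spots with a flag of 0, per the labels. The labels do not name the log base or the direction. Values were centred near 0, with scan medians of -0.04, 0.01 and -0.02 at high power and -0.01, 0.02 and -0.02 at low power, and they ran from -5.42 to 3.67. The labels also describe values merged from both scans in GeneSpring, which were not used here. Scanner model, array design, background correction and signal intensities are not given in the sources used here, so signal over background is unknown. LOWESS sets the average ratio at each brightness to 0, so a shift common to most transcripts would not appear in these values.

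The table holds 6912 spots. The platform annotation names a gene for 5513 of them and none for 1399, and no spot has several genes. Through the R64 assembly's gene table all but 5 of the named spots received a current symbol, which gave 5365 genes. That table was used for names, coding length and gene order, and no coordinates are given, because the files name no build. At high power 6104, 4121 and 5100 spots had a value on replicates 1, 2 and 3, and at low power 3871, 1737 and 2054. Some values appear to have been averaged per gene before deposit: of 96 genes with 2 spots, 65 held the same values in both spots in every column, and all 49 spots of ACT1 held the same values.

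For each hybridization the high and low scans of a spot were averaged where both had a value, since a rescan is not a replicate, and spots of a gene were averaged. Among the 31 genes whose 2 spots differed, the median difference was 0.27 and the highest 1.48 on the log2 scale. The 3642 genes with a value on all 3 hybridizations were tested against 0 with limma 3.58.1 in R 4.3.3 (a fit of the mean, eBayes moderation, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). With 3 hybridizations an exact sign-flip test of a single gene cannot go below p = 0.25, so calls rest on the spread shared across genes.

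Before the data were examined, 27 gene lists were fixed, and 26 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01. They cover checkpoint targets, base excision and nucleotide excision repair, Yap1 targets, glutathione, sulfate and methionine, proteasome, heat shock, general stress, ribosomal proteins, ribosome biogenesis, aldehyde and alcohol dehydrogenases, multidrug transport, glycolysis, hexose transport, respiration, histones, both cell cycle lists, Gcn4 targets, ergosterol, the unfolded protein response, iron, phosphate, vitamins, and mating and meiosis genes, chosen as markers of other cell types, though the measured mating genes are ones that haploid cells of this strain can express and so cannot serve as such. Alternatives to the preset test were an estimated correlation, fry, and the percentile of the list median among 10000 random lists of the same size. Members were also counted with p adjusted over the list alone.

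Genes are named by a rule fixed at the same time: up to 12 genes in each direction past the threshold with the same sign on all 3 hybridizations, the 2 measured members of each list with the smallest p, and HUG1, RNR3, MAG1 and GSH1 always. Any other gene is said to be named after its values were seen, except members that passed adjusted over their list alone, which are named to complete those counts.

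The procedure was tested on simulated data with 3642 genes and 200 of them changed, over 20 simulations. It recovered 35.0% of genes changed by a log2 ratio of 1, 80.1% of those changed by 2 and 93.0% of those changed by 3, and 2.97% of its calls were false. Noise was drawn independently for each gene, without differences by spot position or correlation between genes. With fewer changed genes the adjustment is also stricter, so these shares need not hold for the arrays themselves. For lists, the preset test found a list shifted by 0.6 in 100% of 50 simulations, and the test with an estimated correlation in 0% of them. When all 26 lists were left unchanged but their members shared random shifts on each array (SD 0.5), the preset test called 13.5 lists on average, and the test with an estimated correlation called 0.

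Alternatives tried were either scan alone, genes with a value in both scans, genes on at least 2 hybridizations, centring, scaling, each replicate left out, trended and robust moderation, no moderation, array weights, a test against a 1.5-fold change, all 6 scans with the hybridization as a block, and the median over spots. Taking out the median of each of 192 spot groups, formed from the first 2 indices of the spot number (8 by 24), was added after seeing the data, as was a test of spots without a gene name. The meaning of the spot number's indices is not given in the sources used here.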

Results

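Exponentially growing cells of the budding yeast Saccharomyces cerevisiae, strain S288C, were exposed to chloroacetaldehyde, a chlorinated aldehyde that reacts with nucleic acid bases and with thiols. The compound was added at 25 ppm to cultures at an optical density of 1 in rich glucose medium at 25 °C, and the cells were collected after 2 h. Polyadenylated RNA of the exposed cells, labelled with Cy5, was hybridized to cDNA arrays against RNA taken before the exposure, labelled with Cy3. There were 3 such hybridizations, from independent biological samples, and each was scanned at high and at low laser power. The comparison asks which transcripts differed between exposed cells and the cells before exposure.

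Values are log2 ratios of exposed over before. The base of the logarithm and the direction are not given in the sources used here: the base was read as 2, and the direction is the likely one, since the labels list the exposed sample as channel 1 and the earlier sample as channel 2. If the ratios run the other way, every sign below turns. Every array had the same dye order, and the exposed cells had also grown for 2 h longer, so dye and time of growth cannot be told apart from the exposure. Means are given with the SD over the 3 hybridizations (n = 3 throughout), and the number of arrays limits the precision.

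The sulfite exporter gene SSU1 (YPL092W) rose after exposure, by 2.69 ± 0.12 on the log2 scale, or 6.46-fold (adjusted p = 0.00317, limma with Benjamini-Hochberg adjustment). Its values on the hybridizations were 2.79, 2.56 and 2.72. EEB1 (YPL095C), which encodes an acyltransferase that makes fatty acid ethyl esters, fell, with a mean of -2.24 ± 0.45, or 4.72-fold lower (adjusted p = 0.0201), and values of -2.43, -2.56 and -1.73. These were the 2 genes past the threshold among 3642 genes measured on all 3 hybridizations. Without replicate 1 there were 0, without replicate 2 there was 1 (SSU1), and without replicate 3 there were 12. With trended and robust moderation or with none, 0 passed. The trend took the mean log2 ratio itself as covariate, and a test without moderation has little power on 3 arrays. These settings therefore do not decide whether the calls hold. Over settings of scan, genes tested, scaling, position and left-out replicate the adjusted p ran from 0.00160 to 0.166 for SSU1, the latter without replicate 1 at a mean of 2.64, and from 0.00180 to 0.232 for EEB1, which lost its call under 3 settings at a similar fold. Its mean was -2.14 ± 0.59 without replicate 1 (adjusted p = 0.232), -2.08 ± 0.50 without replicate 2 (adjusted p = 0.143) and -2.03 ± 0.37 once the median of each group of neighbouring spot numbers was taken out (adjusted p = 0.0574, a setting chosen after seeing the data).

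Beyond SSU1 and EEB1, 8 more genes differed more than 2-fold in the same direction on all 3 hybridizations without passing the test. Of these, YNL134C, YNR064C and ATO3 were chosen after their values were seen. Higher were the methylglyoxal reductase gene GRE2 (2.14 ± 0.90), the aryl-alcohol dehydrogenase gene AAD6 (1.99 ± 1.02), the small heat shock protein gene HSP12 (1.68 ± 0.80), the cell wall glycoprotein gene YGP1 (1.60 ± 0.51), YNL134C (1.38 ± 0.28) and YNR064C (1.34 ± 0.25). Lower were the putative ammonium transporter gene ATO3 (-1.54 ± 0.22) and the siderophore transporter gene ARN2 (-1.31 ± 0.43). Their adjusted p ranged from 0.110 for ATO3 to 0.160 for ARN2. In all, 22 genes had an adjusted p under 0.2, 15 higher and 7 lower. At an unadjusted p under 0.05 there were 224 genes, 101 higher and 123 lower, where 182 are expected by chance.

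**Figure D1:**
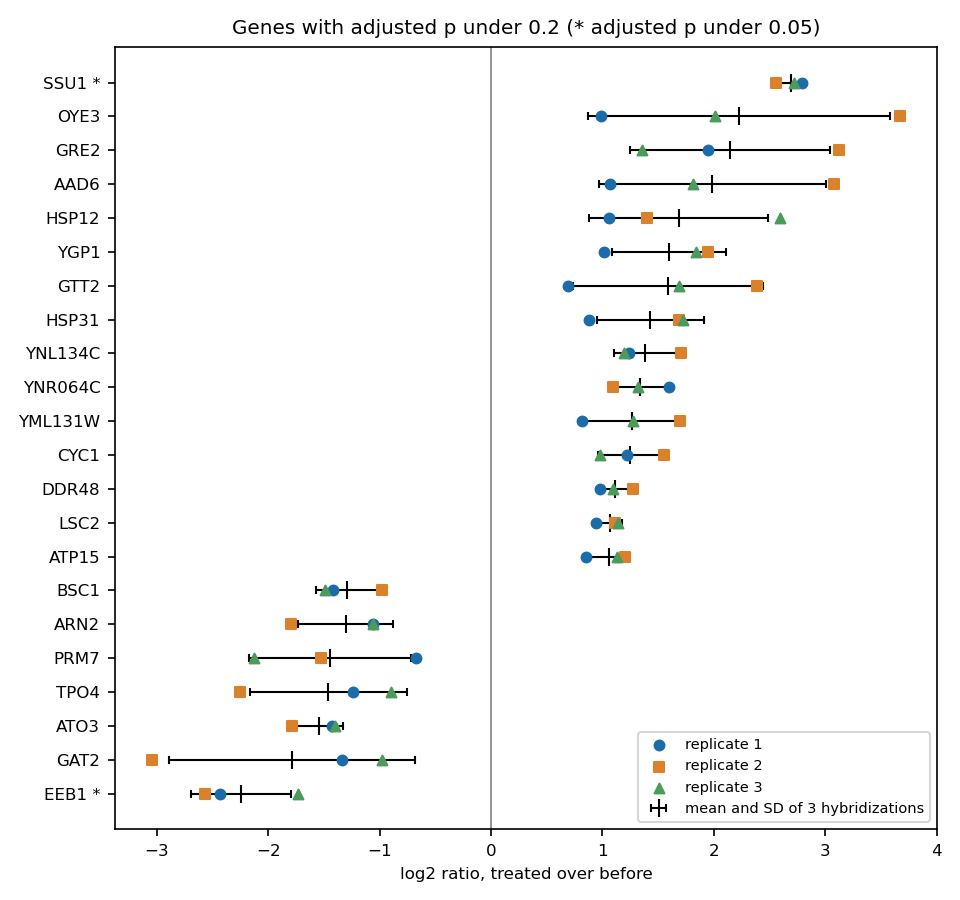
Log2 ratio of exposed over before (horizontal axis) for the 22 genes with an adjusted p under 0.2, with a coloured point per replicate, a black tick for the mean and a bar for the SD of the 3 hybridizations. SSU1 lies between 2.56 and 2.79 on every hybridization, while OYE3 spans 0.99 to 3.67.

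Across genes the hybridizations agreed poorly, although repeat scans of each agreed well. The correlation of log2 ratios was 0.206 between replicates 1 and 2, -0.0537 between 1 and 3, and 0.0698 between 2 and 3, over 3642 genes, which are not independent of each other. The high and low scans of a hybridization correlated at 0.925, 0.921 and 0.937. Of the genes, 1003 had the same sign on all 3 hybridizations, or 27.5%, where chance gives 25%. The median SD of a gene was 0.38. The median 95% confidence interval reached 0.55 to either side of the mean, without adjustment for the number of genes. Differences smaller than that were mostly not detectable with these arrays, and a call adjusted over 3642 genes needed far larger ones. GRE2 at 2.14 ± 0.90 and ATO3 at -1.54 ± 0.22 did not pass (limma, adjusted p = 0.117 and 0.110).

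**Figure D2:**
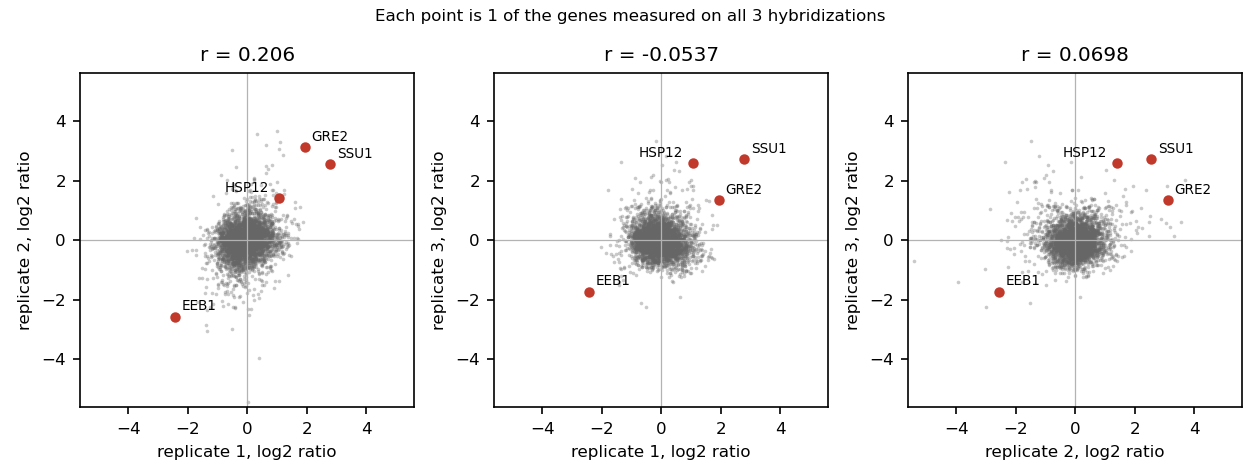
Log2 ratios of the 3642 genes on each pair of hybridizations, with a grey point per gene and 4 genes marked in red. The correlations above the panels are 0.206, -0.0537 and 0.0698, and SSU1 and EEB1 lie far from the cloud in all panels.

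Targets of the oxidative stress factor Yap1 and respiratory genes had the highest medians among the gene lists, 0.63 and 0.38, and heat shock chaperones the lowest, -0.36. These were the lists whose preset calls, given with each list, held under the most settings. The lists, fixed before the data were examined, were set against all other genes with limma's camera test. With the preset correlation, 11 of 26 lists passed, 7 higher and 4 lower. None passed with an estimated correlation (0 at an adjusted p under 0.05, and 0 at an unadjusted p under 0.05). For each of the 11 lists the adjusted p of that test was 0.808, a tie made by the adjustment. Its unadjusted p ran from 0.0525 for heat shock chaperones, with Yap1 targets at 0.0928, to 0.560 for ribosomal proteins. By limma's fry test for movement in 1 direction 0 lists passed, while fry's test for change in either direction called 3 lists. Set against random lists of the same size, which like the preset test takes little account of correlation between genes, 10 list medians passed. With 3 arrays the test with an estimated correlation has little power: it found 0% of simulated lists shifted by 0.6, although their members were simulated independently. A call lost there does not show that a list stayed level, and it is no evidence against any list below. The preset test can call too many, since it called 13.5 lists on average in simulations where members only shared random shifts on each array. Those shifts had an SD of 0.5. Among the 11 lists the SD of the hybridization medians ran from 0.126 (heat shock chaperones) to 0.609 (iron), with 0.427 for Yap1 targets and 0.326 for respiratory genes. The simulated rate therefore need not hold for lists that varied less. Only 4 of the 11 lists had a median of the same sign on every hybridization. When the sign of replicate 1, 2 or 3 was turned, the preset test called 12, 10 and 7 lists in turn, so the number of calls alone does not show a common direction. Outside SSU1 and EEB1, which are in none of the lists, no list member passed over all genes, and 21 different members passed when p was adjusted over the list alone (10 without replicate 2 and 45 without replicate 3).

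Targets of Yap1, the transcription factor of the oxidative stress response, had the highest list median. The median over 20 measured members was 0.63, with 0.32, 1.17 and 0.65 on the hybridizations; 17 members had a positive mean, and 14 were higher on every hybridization. The list stood above the other genes with the preset correlation (adjusted p = 4.13e-13), but not with the correlation taken from the data: adjusted p = 0.808 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 8 did, all higher. They were GRE2, AAD6, the glutathione S-transferase gene GTT2 (1.59 ± 0.85), the glutathione reductase gene GLR1 (0.98 ± 0.48), AAD3 (1.60 ± 1.13), the NADPH oxidoreductase genes OYE3 (2.22 ± 1.35) and OYE2 (1.10 ± 1.00), and the thioredoxin gene TRX2 (1.09 ± 0.72). AAD genes are close copies of each other, and a cDNA spot for one can bind RNA of another. The preset call held under 9 of 10 other settings of scan, genes tested, scaling, position and left-out replicate, with an adjusted p from 7.23e-18 to 0.0594, the latter over genes with a value in both scans.

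Aldehyde and alcohol dehydrogenases and reductases and glutathione genes overlapped with the Yap1 list. Among 20 measured dehydrogenases and reductases, 14 had a positive mean, the list median was 0.08, and 4 passed adjusted over the list alone (0 over all genes): GRE2, AAD6, AAD3 and the glycerol dehydrogenase gene GCY1 (1.15 ± 0.51). Without the 4 members shared with the Yap1 list the median was 0.04. Its medians on the hybridizations were -0.24, 0.14 and 0.81, and the list median was 0.37 without replicate 1, 0.28 without replicate 2 and -0.09 without replicate 3 (adjusted p = 0.159). Among 22 glutathione genes, 17 had a positive mean, the median was 0.16, and GTT2 and GLR1 passed adjusted over the list alone (0 over all genes). The glutathione median was 0.14 without the 3 members shared with the Yap1 list, and 14 of the other 19 had a positive mean. GSH1, the gene of the first enzyme of glutathione synthesis, had 0.15 ± 0.30. Both lists passed with the preset correlation (adjusted p = 0.000764 and 0.00227), and each had an adjusted p = 0.808 with an estimated correlation. Among random lists of the same size the dehydrogenase median lay at percentile 92.97, which did not pass, and the glutathione median at percentile 99.59. Over the other settings the preset adjusted p ran from 8.57e-06 to 0.201 for dehydrogenases and from 0.000115 to 0.390 for glutathione genes. The glutathione call was lost without replicate 3 (adjusted p = 0.0539), with the low-power scan alone (0.389) and over genes with a value in both scans (0.390). Glutathione medians on the hybridizations were -0.06, 0.26 and 0.30, and 6 of 22 members were higher on every hybridization. The glutathione median was 0.24 without replicate 1, 0.08 without replicate 2 and 0.14 without replicate 3.

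Genes of the tricarboxylic acid cycle and the respiratory chain stood above the other genes. Of 41 measured members, 31 had a positive mean and 20 were higher on every hybridization, and the median was 0.38, with 0.03, 0.24 and 0.67 on the hybridizations. Adjusted over the list alone 4 members passed (0 over all genes), all higher: the cytochrome c gene CYC1 (1.25 ± 0.29), the succinyl-CoA ligase gene LSC2 (1.07 ± 0.11), the ATP synthase gene ATP15 (1.06 ± 0.18) and the succinate dehydrogenase gene SDH2 (0.94 ± 0.25). The preset call (adjusted p = 2.79e-10) held under 10 of 10 other settings, but the list had an adjusted p = 0.808 with an estimated correlation. The size depended on replicate 3, without which the median was 0.18 (adjusted p = 0.00424). By fry, its members changed in either direction (adjusted p = 0.0113).

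Glycolytic and fermentation genes lay below the other genes, mainly on replicate 1. Of 19 measured, 16 had a negative mean, and the median was -0.28, with -1.001, -0.09 and 0.15 on the hybridizations. The enolase gene ENO2 had -0.87 ± 1.00 and the pyruvate decarboxylase gene PDC1 -0.86 ± 0.85; 0 members passed over all genes or adjusted over the list alone. The preset call (adjusted p = 0.0227) was lost without replicate 1, at a median of 0.09 (adjusted p = 0.451), against -0.52 without replicate 3. With an estimated correlation, a test with little power here, the adjusted p was 0.808. The preset adjusted p ran from 2.17e-05 to 0.451 over the other settings. Hexose transporters had a median of 0.00 over 10 members, with 0.03, -0.78 and 0.63 on the hybridizations and no call (median 0.31, adjusted p = 0.00950, without replicate 2 and -0.42, adjusted p = 0.0287, without replicate 3); HXT5 had -0.87 ± 1.41 and HXT6 0.73 ± 1.53, and 0 members passed over all genes or adjusted over the list alone.

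Heat shock chaperones had a negative median on every hybridization. Of 19 measured members, 16 had a negative mean and 10 were lower on every hybridization, and the median was -0.36, with -0.46, -0.29 and -0.21 on the hybridizations. FES1, which encodes a nucleotide exchange factor of cytosolic Hsp70, had -0.73 ± 0.16. The single member past the threshold adjusted over the list alone (0 over all genes) went the other way: HSP12, a membrane-associated small heat shock protein gene also on the general stress list. The preset call (adjusted p = 0.000764) held under 10 of 10 other settings but not with an estimated correlation (adjusted p = 0.808). That estimate was -0.0141, below the preset 0.01, so correlated members do not account for the lost call. On 3 arrays the test with an estimated correlation has little power. Fry called change in either direction (adjusted p = 0.0113).

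Msn2/Msn4 general stress genes differed in sign between hybridizations. Over 23 members the medians were -0.43, -0.96 and 1.33, and the median of the means was 0.05 (no call, adjusted p = 0.822 by camera). Without replicate 2 the median was 0.36, and without replicate 3 it was -0.65 (adjusted p = 6.83e-05 and 1.11e-06, preset correlation alone), against 0.12 without replicate 1. HSP12 and YGP1 passed adjusted over the list alone, and 0 members passed over all genes.

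Other stress lists did not pass. The unfolded protein response list had a median of 0.14 over 14 members (0.01 without replicate 2 and 0.01 without replicate 3), with SIL1, an endoplasmic reticulum chaperone cofactor gene, at 0.76 ± 0.35 and FPR2 at 0.73 ± 0.40; fry called change in either direction (adjusted p = 0.000580), and 0 members passed over all genes or adjusted over the list alone. Proteasome genes had a median of -0.04 over 36 members (-0.14 without replicate 2 and 0.01 without replicate 3), with UMP1 at 0.54 ± 0.23 and RPN1 at -0.53 ± 0.22, and 0 passed over all genes or adjusted over the list alone.

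No list of DNA damage or repair genes passed, by camera or fry. Targets of the DNA damage checkpoint had a median of -0.09 over 8 measured of 20 members (adjusted p = 0.911 by camera). Base excision and translesion repair genes had 0.06 over 11 of 20 (adjusted p = 0.964 by camera). Nucleotide excision and recombination repair genes had -0.12 over 8 of 23 (adjusted p = 0.354 by camera). Of the measured members of these lists, 0 passed over all genes or adjusted over the list alone, and nothing is said of the others. The mean of the base excision list was -0.02, of opposite sign to its median, and the median itself was -0.05, -0.04 and -0.04 without replicates 1, 2 and 3 in turn. With a replicate left out the medians ran from -0.18 to -0.03 for checkpoint targets and from -0.25 to -0.03 for nucleotide excision genes, without a call. The ribonucleotide reductase gene RNR2 had 0.55 ± 0.42 and the repressor gene RFX1 -0.26 ± 0.31. The 3-methyladenine glycosylase gene MAG1 had 0.02 ± 0.43, RAD6 -0.50 ± 0.30, UBC13 0.45 ± 0.39, RAD1 -0.53 ± 0.10 and RAD55 -0.52 ± 0.17. HUG1 had a value on replicate 1 alone (0.12), and RNR3 on replicates 1 (-0.75) and 3 (-0.04), so neither could be tested. The checkpoint targets DDI2, DDI3 and RAD54, named after their values were seen, also lacked a value on 1 hybridization. Their high-power values were 0.30 and 1.05 (DDI2, replicates 1 and 3), -0.27 and 0.50 (DDI3, replicates 1 and 2) and -0.01 and -0.27 (RAD54, replicates 1 and 3). RAD54 also had a low-power value on replicate 1, which was 0.17, of opposite sign to the high-power value there.

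Histone genes were higher mainly on replicate 1. Of 9 measured, 8 had a positive mean, and the median was 0.33, with 0.86, -0.01 and 0.19 on the hybridizations; HHF1 had 0.66 ± 0.48 and HTB1 0.49 ± 0.23, and 0 members passed over all genes or adjusted over the list alone. The preset call (adjusted p = 0.00736) did not hold with an estimated correlation (adjusted p = 0.808), a test with little power here. Over the other settings the adjusted p ran from 4.66e-05 to 0.421: without replicate 1 the median was 0.06 (adjusted p = 0.421), without replicate 2 it was 0.50, without replicate 3 the adjusted p was 0.0546 at a median of 0.30, and with group medians of spots taken out it was 0.0657 at a median of 0.18. Cell cycle lists did not pass. G1 and S phase genes had a median of 0.13 over 12 members, with RNR1 at 0.71 ± 0.68 and GIC2 at 0.41 ± 0.53, and G2, M and early G1 genes had 0.12 over 19, with CLN3 at -0.70 ± 0.20 and SIC1 at -0.38 ± 0.21 (with a replicate left out the medians ran from 0.08 to 0.21 and from 0.05 to 0.17); 0 members of either passed over all genes or adjusted over the list alone.

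Cytosolic ribosomal protein genes stood slightly above the other genes. Of 115 measured, 71 had a positive mean and 44 a negative one, the median was 0.08, and the medians on the hybridizations were 0.27, 0.01 and -0.14. RPL9B had 0.81 ± 0.15 and RPP0 -0.62 ± 0.19, and 0 members passed over all genes or adjusted over the list alone. The list passed with the preset correlation (adjusted p = 0.0346), and its median lay at percentile 99.99 of random lists of the same size. It did not pass with an estimated correlation (adjusted p = 0.808). The median was -0.06 without replicate 1, against 0.20 without replicate 3. The preset call held under 3 of 10 other settings, with an adjusted p from 0.000493 to 0.696. Ribosome biogenesis genes had a median of -0.02 over 37 members and no call (-0.13 without replicate 1, -0.16 without replicate 2 and 0.26, adjusted p = 0.00492, without replicate 3), with NOG2 at 0.45 ± 0.26 and NOP1 at -0.51 ± 0.47, and 0 members passed over all genes or adjusted over the list alone.

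Iron regulon genes, which serve iron uptake, had a negative median that came mainly from replicate 2. Of 16 measured, 10 had a negative mean, and the median was -0.29, with 0.23, -0.94 and -0.08 on the hybridizations. Adjusted over the list alone 3 passed, all lower (0 over all genes): ARN2, the siderophore-retaining cell wall protein gene FIT3 (-1.92 ± 1.26) and the ferric reductase gene FRE3 (-0.96 ± 0.64). The preset call (adjusted p = 0.0227) did not hold with an estimated correlation (adjusted p = 0.808), a test with little power here. Over the other settings the preset adjusted p ran from 2.42e-05 to 0.960; without replicate 2 the list median was -0.07 (adjusted p = 0.960), without replicates 1 and 3 in turn it was -0.39 and -0.39, and with the low-power scan alone it was 0.09.

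Multidrug transporters and targets of Pdr1 and Pdr3 had a median of 0.15 over 18 members, with 0.21, 0.57 and 0.20 on the hybridizations, and 11 members had a positive mean. Adjusted over the list alone 3 passed (0 over all genes): GRE2 and the transporter gene AQR1 (1.03 ± 0.46), both higher, and the polyamine transporter gene TPO4 (-1.46 ± 0.71), which was lower. Gcn4 targets of amino acid biosynthesis had a median of -0.17 over 39 members, 28 of them with a negative mean, and medians of -0.49, 0.14 and -0.14 on the hybridizations. THR1 had -0.67 ± 0.06 and ILV5 -0.75 ± 0.66, and 0 members passed over all genes or adjusted over the list alone. Preset calls of both lists (adjusted p = 0.0227 and 0.0284) did not hold with an estimated correlation (adjusted p = 0.808 for each), a test with little power here. The estimate was 0.0171 for the multidrug list, near the preset 0.01, and 0.256 for Gcn4 targets. Over the other settings the preset adjusted p ran from 0.0165 to 0.677 and from 7.48e-05 to 0.824. The multidrug call was lost without replicate 1 (median 0.25, adjusted p = 0.0704) and without replicate 2 (median 0.05, adjusted p = 0.0721), and without replicate 3 the median was 0.29. The Gcn4 call was lost without replicate 1 (median -0.06, adjusted p = 0.824) and without replicate 3 (median -0.15, adjusted p = 0.121), and without replicate 2 the median was -0.29.

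Remaining metabolic lists did not pass. Sulfate assimilation and methionine genes had a median of 0.16 over 16 members, with -0.54, 0.80 and 0.21 on the hybridizations; SAM2 had 0.74 ± 0.86 and MET16 0.50 ± 0.36. Without replicate 1 this list and the phosphate list passed the preset test, with medians of 0.50 and 0.26 (adjusted p = 0.000981 and 0.00106), and without replicate 2 their medians were -0.12 and -0.17. Phosphate regulon genes had 0.02 over 14 members, with the acid phosphatase gene PHO5 at 1.42 ± 1.53 and PHM6 at 0.57 ± 1.11. Without replicate 2 these genes had means of 0.53 and 0.01. Ergosterol synthesis genes had -0.17 over 23 members, with NCP1 at -0.59 ± 0.24 and ERG10 at 0.45 ± 0.30, and vitamin B1 and B6 genes 0.05 over 10, with SNZ2 at 0.44 ± 0.17 and THI13 at 0.37 ± 0.05. Without replicate 1 the ergosterol median was -0.02, and the vitamin median was 0.23 without replicate 1 and -0.17 without replicate 3. In these 4 lists 0 members passed over all genes or adjusted over the list alone.

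Mating and pheromone genes had a median of -0.14 over 9 members and no call (adjusted p = 0.109). The median was -0.17 without replicate 1 (adjusted p = 0.0470), -0.24 without replicate 2 (adjusted p = 0.0438) and -0.08 without replicate 3. The agglutinin gene SAG1 (-1.10 ± 0.36) passed adjusted over the list alone, 0 members passed over all genes, and the pheromone receptor gene STE3 had -0.72 ± 0.51. Only 2 meiosis and sporulation genes were measured, too few to test: DMC1 had 0.34 ± 0.32 and SPS100 0.17 ± 0.82.

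**Figure D3:**
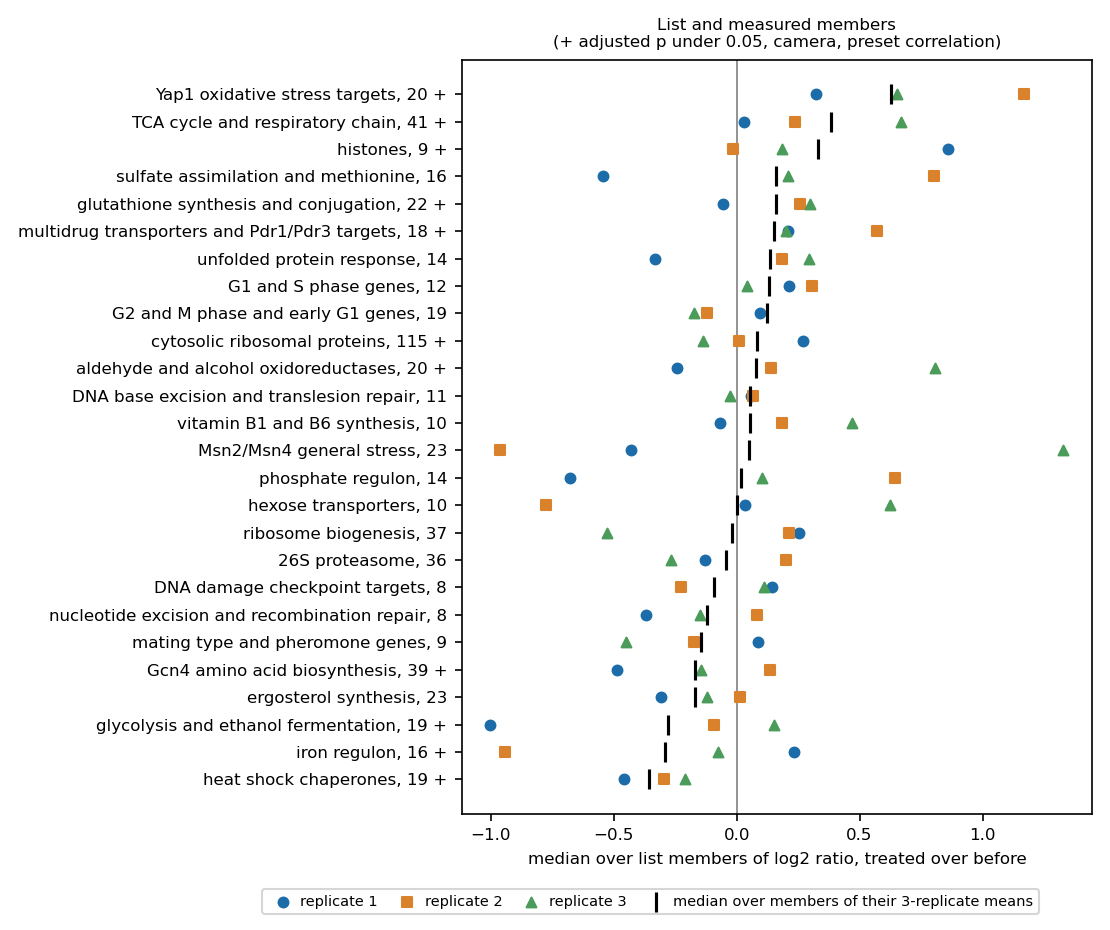
Median log2 ratio of exposed over before over the measured members of each of the 26 lists (horizontal axis), with a coloured point per replicate, a black tick for the median over the members' means, and the number of measured members after each name. The Yap1 list lies at 0.32, 1.17 and 0.65 on the hybridizations, and the general stress list at -0.43, -0.96 and 1.33.

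Medians of the log2 ratio differed between groups of spots, most on replicate 1. When spots were grouped by the leading digits of their spot number into 192 groups, group membership accounted for 26.5%, 2.38% and 7.28% of the variance of the spots' values on the hybridizations (adjusted for the number of groups), against at most 0.910% in 50 shuffles of any hybridization. Longer genes had lower values on replicate 1, with a correlation across genes, which are not independent, of -0.332 between log2 ratio and coding length, against -0.0495 and -0.177 on the others. Groups with an odd second index held genes with a median coding length of 939 bp and those with an even one of 1836 bp. The groups thus differ in gene content as well as place, and length and place were not separated. With group medians taken out, the histone median went from 0.33 (quartiles 0.11 and 0.40) to 0.18 (0.18 and 0.34) and its adjusted p from 0.00736 to 0.0657. The ribosomal protein median went from 0.08 (-0.11 and 0.24) to 0.07 (-0.10 and 0.21) and its adjusted p from 0.0346 to 0.0930, and EEB1 from -2.24 ± 0.45 to -2.03 ± 0.37 and from 0.0201 to 0.0574. For ribosomal proteins and EEB1 the size barely moved while the adjusted p crossed the threshold, so these lost calls are no evidence of position as the cause. Whether gene length contributes to the histone and ribosomal protein medians was not tested.

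**Figure D4:**
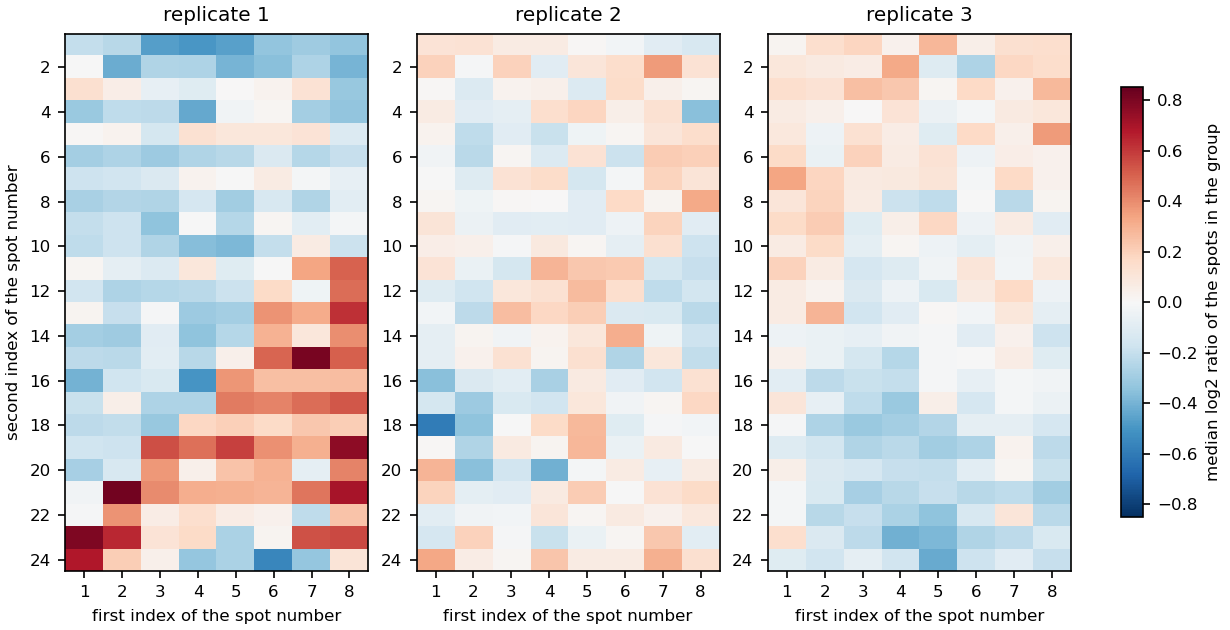
Median log2 ratio of the spots in each of the 192 groups formed by the first and second index of the spot number (axes), with a panel per replicate and colour for the median. Group medians run from -0.56 to 0.82 on replicate 1, from -0.59 to 0.37 on replicate 2 and from -0.43 to 0.36 on replicate 3.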

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

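The position setting and the test of spots without a gene name were chosen after seeing the data, and the others before. SSU1 and EEB1 were the genes past the threshold with the high-power scan alone, with genes on at least 2 hybridizations, and with centring or scaling. Neither had a value in all low-power scans, and the low-power scan gave 2 other genes (GRE2 and YGP1), and genes with a value in both scans gave 4 (YGP1, YNL134C, BSC1 and TPO4). Leaving out a replicate gave 0 to 12 genes, 0 without replicate 1, 1 without replicate 2 and 12 without replicate 3. Position medians left 1 gene, a test against a 1.5-fold change 1, trended and robust moderation 0, no moderation 0 and all 6 scans as a block 7. What caused these differences was not tested. The trend had the mean log2 ratio as covariate and the test without moderation has little power, so their counts of 0 do not decide whether a call holds.

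Among lists, 7 passed with the high-power scan, 5 with the low-power scan, 2 over genes with a value in both scans, 0 with an estimated correlation, 0 by fry and 10 against random lists. Members past adjusted over the list alone numbered 5 with the low-power scan, 7 over genes in both scans, and 10 to 45 with a replicate left out. Mean replicate correlation ran from -0.0537 to 0.206 with a replicate left out, and scan correlation was 0.944 over genes in both scans and 0.882 with position medians taken out.

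Lists with a call in the main test or in the setting changed sign as follows: with the low-power scan multidrug transport (-0.00102) and iron (0.0941), and over genes in both scans iron (0.0152). With a replicate left out the medians ran from -0.0643 to 0.197 for ribosomal proteins, -0.516 to 0.0905 for glycolysis, -0.65 to 0.36 for general stress, -0.16 to 0.26 for ribosome biogenesis, -0.0906 to 0.372 for dehydrogenases and -0.42 to 0.31 for hexose transporters. The cause was not tested. Of values for single genes and lists, 639 kept their sign and side of the threshold, 29 lost a call, 13 gained one and 9 changed sign with a call in either setting. Another 23 changed sign without a call in either, among them ergosterol genes over genes in both scans (0.105), sulfate genes without replicate 2 (-0.121), HXT6 without replicate 3 (-0.0646) and MAG1 with the low-power scan (-0.0845). The unknown signal over background limits how far scan-dependent changes can be traced.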

Other observations

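The setting with group medians of spots taken out was added after seeing the data; the bounds for the general stress, respiratory and Yap1 lists in it were written before its values were computed. Tests on the low correlation between hybridizations, on gene order, on unnamed spots and on a turned sign for the general stress genes were chosen after the results were seen, and those on gene length and turned-sign counts before. Beyond the lists, several genes with an adjusted p under 0.2 stood apart on every hybridization, and they are named here after their values were seen. None passed the threshold. The stress-related gene DDR48 had 1.12 ± 0.15 (SD, n = 3), HSP31, which encodes a methylglyoxalase, 1.43 ± 0.48, and YML131W, an open reading frame similar to reductases, 1.26 ± 0.44. Among lower genes, the GATA-type factor gene GAT2 had -1.79 ± 1.10, PRM7 -1.44 ± 0.73 and BSC1 -1.29 ± 0.28. ECM4, a glutathione transferase gene on the Yap1 list without a value on replicate 3, had 0.30 on replicate 1 and 2.07 on replicate 2. The general stress gene PGM2, without a value on replicate 2, had high-power values of -1.09 and 1.14 on replicates 1 and 3, and HSP26 had -0.44 and 1.90.

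It was noticed after the test that both genes past the threshold lie on chromosome XVI, 3 gene places apart with opposite signs; 0.103% of pairs of tested genes on all chromosomes lie as close. The 2 genes between them had means of 0.10 (SEC62) and 0.34 (NOG1), and GLR1, next to SSU1 on its other side, had 0.98. Among 124 tested spots without a gene name 0 passed in limma, 4 had an unadjusted p under 0.05, and the smallest adjusted p was 0.561.

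The hybridizations correlated at 0.0739 on average across genes, against 0.928 for scans. Taking out group medians of spots gave 0.0999 (95% bootstrap interval over genes, which are not independent, 0.0650 to 0.138). This argues against spot position as the whole cause. Turning a sign leaves the size of a correlation unchanged, and the largest was 0.206 (0.171 to 0.241). A hybridization deposited with its sign turned is thus argued against as the cause of the small correlations. Whether a sign was turned cannot be read from sizes this small. Genes with a value in both scans, taken as the brighter spots, reached 0.114 (0.0598 to 0.172), which argues against dim spots as the whole cause. Biological differences between the cultures and the handling of each array stay open, and the labels give no variable to test them.

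General stress genes lay at -0.96 on replicate 2 and 1.33 on replicate 3, a gap of 2.29. With group medians of spots taken out the gap was 2.29 (1.43 to 2.74), where position as the cause needed under 0.5, a level set beforehand, so position is argued against as the whole cause. The interval does reach below the 1.5 set beforehand for excluding it, and resting the exclusion on 0.5 was decided after the interval was seen. A turned sign on either hybridization would also turn the Yap1 targets, whose lower median on these hybridizations was 0.65 (0.31 to 0.90, again over list members), so it is argued against. A candidate explanation is a difference in growth stage or handling between the cultures, a hypothesis for which no biological variable was tested.

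Respiratory genes and Yap1 targets stood above the other genes with the preset correlation, but each had an adjusted p = 0.808 with an estimated correlation. Their medians lay at percentile 100 and percentile 100 of 10000 random lists matched on coding length. With group medians of spots taken out they were 0.32 (0.23 to 0.42) and 0.62 (0.33 to 1.24). On replicates 1, 2 and 3 in turn they were then 0.03, 0.19 and 0.67 for respiratory genes and 0.30, 1.09 and 0.64 for Yap1 targets. The pooled values argue against length and position as the whole cause on these 3 arrays. A response to chloroacetaldehyde may explain both shifts, as a hypothesis found and tested on the same data; dye and 2 h of growth stay open, because no array separates them from the exposure, and so does a difference between cultures for the respiratory list, whose median was 0.03 on replicate 1, 0.67 on replicate 3 and 0.18 with replicate 3 left out. Turning signs gave as many lists in 2 of 4 patterns (11 as deposited, and 12, 10 and 7 with replicates 1, 2 and 3 turned in turn). It gave as many genes in 1 of 4 (2 as deposited, 0 at the highest of the others). With 4 patterns no share under 0.05 can be reached.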
